A study of Drosophila melanogaster with 12 samples.

How the data were processed

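RNA sequencing was carried out on midguts dissected from virgin female Drosophila melanogaster, with 10 guts per sample. The flies developed at 18 °C and were held at 29 °C for 10 days as adults, a shift that inactivates the temperature-sensitive GAL80 repressor and so lets GAL4 act. Of the 2 drivers, esg-GAL4 acts in intestinal progenitors (stem cells and their undifferentiated daughters) and Myo1A-GAL4 acts in enterocytes, the absorptive cells. With each driver, flies carrying UAS-ImdD30A, a form of the adaptor Imd that the series describes as suppressing the pathway, were set against driver flies without that transgene. The 12 libraries fall into 4 groups of 3, which the labels call biological replicates. Control flies carried the driver, GAL80 and UAS-GFP but no ImdD30A insertion, so the presence of the insertion and its chromosome goes with the group.

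Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic, aligned with HISAT2 2.1.0 and handled with SAMtools 1.8, and edgeR was used for the comparisons. The counting tool, its use of strand and its treatment of reads that match several genes are not given in the sources used here. The authors deposited raw read counts per gene, not normalised, in 1 table for each driver, each with 17737 genes. They also deposited the gene annotation of genome build BDGP6, release 95 per its name, and the identifiers of all 17737 genes matched it; positions and symbols are taken from it and counted from 1. The authors' deposited table of each comparison holds log2 fold changes and log2 mean expression made with edgeR per the file headers and the submitters' processing notes. It also gives a p-value and an FDR per gene, per the file headers, for 9506 genes; which edgeR test gave them is not given in the sources used here. Mean expression was identical in the tables of both drivers, as in a fit of all 12 libraries at once. All columns of the count tables were assigned to a labelled library by name.

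The total count per library lay between 29763919 and 43300848 and is given by group in the results. A floor of 3 counts corresponds to 0.101 counts per 1e6 counts (CPM) in the shallowest library and to 0.069 in the deepest; such floors cover counting error only, because reads without molecular identifiers are not independent molecules. The 38 mitochondrial genes had 0 counts in all libraries, so mitochondrial transcripts are not measured here. Ribosomal RNA features (140 in the table, by symbol or by location on the rDNA scaffold) were kept. Of the 17737 genes, 2051 share at least 20% of their exon length with another gene, and the 2 members of such a pair cannot be told apart where strand was not used. The same holds for near-identical copies such as LysB, LysD and LysE, Amy-p and Amy-d, PGRP-SC1a and PGRP-SC1b, and the Hsp70 genes.

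Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each driver the 6 libraries were filtered with filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood test (glmQLFit and glmQLFTest), ImdD30A against control, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05 with no minimum fold change. The difference between drivers was the interaction, the Myo1A effect minus the esg effect, in 1 fit of all 12 libraries. Standard errors of log2 fold changes (SE) are the fold change divided by the square root of the F statistic. CPM values are TMM-scaled within a driver and are given as mean ± SD (n = 3 libraries per group). Overlap of calls was tested with Fisher's exact test, two-sided, among genes tested with both drivers.

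Before the data were examined, 39 gene lists were fixed: pathways, digestive and metabolic functions, midgut cell types, and markers of 9 other cell types that a dissection could include. Lists with at least 3 tested members were tested with camera (limma 3.58.1) with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a driver. The camera test was repeated with the correlation estimated from the data. Members called are counted over all genes tested and, separately, adjusted over the list alone. Genes to be named were also fixed by a rule. It took imd, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, and per list up to 4 called members with the smallest p. Where fewer than 2 members of a list were called, up to 2 others with the smallest p were taken, and for the difference between drivers the 4 largest in each direction with a mean of at least 5 CPM.

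Alternatives fixed before the data were examined were DESeq2 1.42.0 and its size factors, limma-voom, no filter on low counts, a filter at 1 CPM in at least 3 libraries, a minimum fold change of 2, a fit of all 12 libraries, the replicate number as a block and each library left out in turn. Leaving out the ribosomal RNA features, testing the lists on the difference between drivers, and a list of ribosome biogenesis genes were chosen after seeing the data. The labels give the groups the same replicate numbers but do not say that a number marks a shared batch.

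The fitting code was tested on simulated counts with 200 genes changed by known amounts, with means and library sizes of the real samples. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 31.3%, 77.6% and 90.9% in the simulated esg comparison of 10145 genes, with 13 false calls among 146. In the simulated Myo1A comparison of 9990 genes it recovered 37.3%, 74.6% and 90.9%, with 9 false calls among 144. For the difference between drivers, simulated over 10347 genes, it recovered 10.4%, 47.8% and 81.8%, with 6 false calls among 99.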

Results

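The 12 libraries profiled whole midguts of flies that carried the esg or the Myo1A driver, with or without UAS-ImdD30A. Total counts per library, in units of 1e6, averaged 32.92 ± 3.84 (SD, n = 3) in the esg controls and 37.81 ± 1.93 in esg with ImdD30A. They averaged 38.56 ± 4.15 in the Myo1A controls and 34.76 ± 5.51 in Myo1A with ImdD30A. Digestive enzymes were among the most abundant transcripts. The trypsin gene alphaTry had 16251.1 to 22053.3 counts per 1e6 counts in the 12 libraries. Ribosomal RNA features took 9.19% to 21.36% of the counts in 11 libraries and 30.21% in replicate 2 of esg with ImdD30A. The first principal component, with 35.3% of the variance, separated the drivers. On the second, with 19%, the Myo1A controls (19.33 to 33.8) lay apart from Myo1A with ImdD30A (-33.12 to -18.31). The esg controls (4.47 to 15.01) and esg with ImdD30A (-18.55 to 5.57) overlapped on it.

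ImdD30A in progenitors addressed how the gut transcriptome changes when this form of Imd is expressed in stem cells and their undifferentiated daughters. imd (FBgn0013983, 2R, 18409796 to 18413599), the adaptor of the pathway, rose from 22.0 ± 0.401 CPM to 65.5 ± 5.41 (SD, n = 3 per group), a log2 fold change of 1.57 ± 0.07 (SE, adjusted p = 0.000237). Reads of the transgene and of the native gene fall on the same gene in this count. w (X, 2790599 to 2796466), the eye pigment transporter gene that also marks many transgene insertions, rose by 4.41 ± 0.10 on the log2 scale (adjusted p = 1.87e-06). Of the genes that fell, CG15263 went from 60.7 ± 4.77 to 10.3 ± 1.89 CPM (-2.56 ± 0.14, adjusted p = 0.000415). rut, an adenylyl cyclase, fell from 49.4 ± 5.46 to 18.6 ± 2.38 CPM (-1.41 ± 0.11, adjusted p = 0.00291).

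With the esg driver 419 of 10107 tested genes were called, 211 higher and 208 lower, and 56 of them changed at least 2-fold (26 higher, 30 lower). The groups did not overlap for 2965 genes, a pattern that chance gives for 10% of genes. The median SE of a log2 fold change was 0.12. Further large rises were those of CG7720 (4.21 ± 0.33), Alp2, an alkaline phosphatase (1.67 ± 0.34), CG3036 (1.56 ± 0.14), CG31041 (1.51 ± 0.17) and CG18179 (1.5 ± 0.24). Further large falls were those of CG11889 and CG11891, which lie on the same exons and hold the same reads (-2.33 ± 0.16), CG16898 (-1.61 ± 0.17) and the muscle actin gene Act79B (-1.43 ± 0.27). Without 1 library the count of called genes was 106 (control 1), 109 (control 2), 169 (ImdD30A 1), 146 (ImdD30A 2) or 239 (ImdD30A 3). DESeq2 called 957, 572 higher and 385 lower, and the fit of 12 libraries 649. The share of higher calls was 50.4% as reported and 59.8% with DESeq2, and ran from 43.2% (without ImdD30A 1) to 58.2% (without ImdD30A 3) with 1 library left out. Of the 50 called genes that the naming rule took for this driver, 21 kept their call whichever library was left out. Without control 1, 2 and 3 it was lost by 24, 26 and 3, and without ImdD30A 1, 2 and 3 by 20, 22 and 14.

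Negative regulators of Imd signalling rose with the esg driver, as a list and singly. PGRP-SC1a, PGRP-SC1b and PGRP-LB encode amidases that degrade peptidoglycan, the bacterial cell wall fragment that triggers the pathway. PGRP-SC1a went from 496 ± 77.9 to 990 ± 91.6 CPM (1.0 ± 0.12, adjusted p = 0.00948). PGRP-SC1b went from 500 ± 65.5 to 894 ± 84.4 CPM (0.84 ± 0.11, adjusted p = 0.0118) and PGRP-LB from 192 ± 16.8 to 280 ± 18.9 CPM (0.55 ± 0.09, adjusted p = 0.0194). Of 12 members 3 rose over all genes and 4 adjusted over the list alone, and none fell (list adjusted p = 0.00271; adjusted p = 0.447 with an estimated correlation). PGRP-SC1a and PGRP-SC1b kept their call without any 1 library. Among 16 signalling components imd alone was called (list adjusted p = 0.0979), and Rel, the NF-kappaB factor of the pathway, had a log2 value of 0.60 ± 0.22 (adjusted p = 0.16).

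Antimicrobial peptide genes, the classical targets of the pathway, were scarcely expressed in any group. Of 15 such genes 14 had a mean below 1 CPM over the 12 libraries, and AttD was highest at 2.63. The filter kept 4 of them with the esg driver and 3 with the Myo1A driver; edgeR called 0 in either comparison over all genes and adjusted over the list alone, with 1 and 0 at an unadjusted p below 0.05. The list tests gave adjusted p = 0.504 and 0.966, the latter pointing down with a median of 0.13. AttD stood at 2.65 ± 0.289 CPM in the esg controls and 6.49 ± 3.64 with ImdD30A (1.30 ± 0.41, adjusted p = 0.117). DESeq2 called AttD higher with the esg driver (adjusted p = 0.00497), and limma-voom called 0 of these genes. In the Myo1A libraries AttD lay the other way, at 1.17 ± 1.01 CPM in the controls and 0.154 ± 0.117 with ImdD30A. Neither edgeR nor DESeq2 called it there. A fall in most antimicrobial peptide genes was not detectable from such low levels, so these genes cannot show whether ImdD30A suppressed the pathway.

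Digestive enzymes split by class with the esg driver. Of 30 trypsins, Jonah proteases and related proteases, 6 rose and 1 fell over all genes, against 21 and 1 adjusted over the list alone (median 0.30, list adjusted p = 1.34e-07; adjusted p = 0.268 with an estimated correlation). Jon99Fi went from 904 ± 119 to 1760 ± 59.3 CPM (0.96 ± 0.10, adjusted p = 0.00643) and Jon65Ai from 823 ± 147 to 1440 ± 25.4 CPM (0.80 ± 0.12), while Ser8 fell (-1.18 ± 0.15, adjusted p = 0.00962). Lysozymes rose too, 3 of 7 over all genes and 4 adjusted over the list alone (list adjusted p = 3.02e-05; adjusted p = 0.268 with an estimated correlation). LysB rose from 5770 ± 547 to 11300 ± 1140 CPM (0.97 ± 0.10, adjusted p = 0.00643), LysE by 0.80 ± 0.14 and LysD by 0.54 ± 0.06. Amylases, maltases and mannosidases, which split starch and sugars, fell in 5 of 18 cases over all genes and in 8 adjusted over the list alone (list adjusted p = 0.00113; adjusted p = 0.431 with an estimated correlation). Among them tobi fell from 4590 ± 271 to 3220 ± 218 CPM (-0.51 ± 0.07) and the amylase Amy-d from 9020 ± 2450 to 4810 ± 228 CPM (-0.91 ± 0.17, adjusted p = 0.0345). Jon99Fi, Ser8 and LysB kept their call without any 1 library. In the fit of 12 libraries LysB, LysD and LysE all lost it, with adjusted p = 0.26, 0.254 and 0.118, the highest over their alternatives.

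Glutathione S-transferases, which conjugate toxic compounds, fell with the esg driver: 6 of 32 over all genes and 8 adjusted over the list alone, none higher (list adjusted p = 7.61e-05; adjusted p = 0.447 with an estimated correlation). GstE1 went from 47.9 ± 8.73 to 18.0 ± 5.03 CPM (-1.41 ± 0.22, adjusted p = 0.0169). GstE10, GstS1 and GstE8 fell by 1.39 ± 0.19, 1.10 ± 0.16 and 0.64 ± 0.08 on the log2 scale. GstE10, GstE1 and GstE8 lie within 2R, 18396638 to 18408955, next to imd, which starts at 18409796. GstS1 lies apart, at 2R, 17093246 to 17099501. Cytochrome P450 genes did not pass as a list (adjusted p = 0.293), yet 7 of 73 fell and 1 rose (8 and 2 adjusted over the list alone). Cyp309a1 went from 322 ± 18.8 to 129 ± 13.5 CPM (-1.32 ± 0.09, adjusted p = 0.00177), Cyp6a23 from 343 ± 8.56 to 172 ± 16.0 CPM (-0.99 ± 0.08, adjusted p = 0.00291) and Cyp6a17 from 44.6 ± 3.9 to 21.9 ± 3.17 CPM (-1.03 ± 0.12). The median of the P450 list was 0.02 and its mean -0.05, with the test in the direction of the mean. Of 15 UDP-glycosyltransferases 2 fell (4 adjusted over the list alone; list adjusted p = 0.139), among them Ugt37b1 (-1.11 ± 0.11, adjusted p = 0.00576). GstE8, Cyp309a1, Cyp6a23, Cyp6a17 and Ugt37b1 kept their call without any 1 library.

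Genes of the unfolded protein response fell with the esg driver: 2 of 14 over all genes, 6 adjusted over the list alone, and all 14 had a log2 value below 0 (list adjusted p = 0.00017; adjusted p = 0.459 with an estimated correlation). Hsc70-3, the chaperone BiP of the endoplasmic reticulum, fell from 795 ± 241 to 347 ± 83.2 CPM (-1.20 ± 0.25, adjusted p = 0.0432) and Herp, a factor of degradation at that organelle, from 139 ± 17.3 to 92.8 ± 1.09 CPM (-0.58 ± 0.10, adjusted p = 0.0208). Genes of lipolysis, lipid transfer and beta-oxidation rose as a list (1 of 15 over all genes, 6 adjusted over the list alone; list adjusted p = 0.000282; adjusted p = 0.268 with an estimated correlation). The called member was LpR1, a lipophorin receptor, which went from 119 ± 9.9 to 186 ± 20.7 CPM (0.64 ± 0.10, adjusted p = 0.0197). Enteroendocrine genes rose as a list (list adjusted p = 3.02e-05; adjusted p = 0.431 with an estimated correlation), with all 18 above 0, 1 called over all genes and 8 adjusted over the list alone. The called gene was AstA, which encodes the gut peptide allatostatin A (31.6 ± 3.1 to 48.9 ± 5.78 CPM, 0.63 ± 0.10, adjusted p = 0.0211).

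Markers of other cell types moved with ImdD30A in the esg comparison. Fat body markers, measured beside the digestive and lipid genes, rose (list adjusted p = 7.11e-05; adjusted p = 0.268 with an estimated correlation), 1 of 5 over all genes and 4 adjusted over the list alone. Yp3, a yolk protein gene, went from 11.3 ± 5.23 to 41.1 ± 11.6 CPM (1.86 ± 0.34, adjusted p = 0.0299). The lipophorin precursor gene apolpp had a log2 value of 1.40 ± 0.36 (adjusted p = 0.0753). Muscle markers passed as a list with 1 of 11 called over all genes and adjusted over the list alone, Mlp60A (0.57 ± 0.12, adjusted p = 0.0459); the list had an adjusted p = 0.0138, and adjusted p = 0.706 with an estimated correlation. Without ImdD30A 3 or control 1 the muscle list had adjusted p = 0.178 or 0.207. Respiratory chain and ATP synthase genes were slightly higher as a list (median 0.08, 0 of 66 called either way, list adjusted p = 0.033; adjusted p = 0.757 with an estimated correlation). That list call ended without ImdD30A 1 (0.134), ImdD30A 2 (0.106), control 2 (0.171) or control 3 (0.147), and at 0.0505 with ribosomal RNA features left out.

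The remaining lists did not pass with the esg driver. In 4 of those not described above 1 member rose over all genes. mira of the progenitor markers, which segregates cell fate determinants in dividing stem cells, went from 3.38 ± 0.367 to 7.18 ± 0.746 CPM (1.09 ± 0.13, adjusted p = 0.00948) and kept its call without any 1 library (list adjusted p = 0.232; 1 adjusted over the list alone). PGRP-SA, a receptor gene of the Toll pathway, rose by 1.09 ± 0.23 (list adjusted p = 0.617, with 1 adjusted over the list alone). Its level was low, 0.651 ± 0.0537 CPM in the controls and 1.38 ± 0.159 with ImdD30A (adjusted p = 0.0469). Lpin, a phosphatidate phosphatase of lipid synthesis, rose by 0.46 ± 0.10 (list adjusted p = 0.0904; 3 higher and 1 lower adjusted over the list alone). REPTOR, a transcription factor held back by TOR, rose by 0.52 ± 0.11 in the insulin and TOR list (list adjusted p = 0.232; 1 adjusted over the list alone). In 3 lists 1 member fell. et of the JAK-STAT genes fell by 0.72 ± 0.13 (list adjusted p = 0.602; 1 higher and 1 lower adjusted over the list alone). Atpalpha, the sodium pump subunit listed with septate junctions, fell by 0.46 ± 0.07 (list adjusted p = 0.232; 1 adjusted over the list alone). GstD1 of the redox genes fell by 0.69 ± 0.12 (list adjusted p = 0.513; 2 higher and 1 lower adjusted over the list alone).

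Lists without a called member over all genes with the esg driver included EGF receptor pathway genes (list adjusted p = 0.0979), Notch targets (0.293), cell cycle genes (0.293), regional factors (0.562) and adhesion genes (0.0828). Enterocyte identity genes (0.0662) had 4 members higher and heat shock genes (0.617) 1 lower adjusted over the list alone. Peritrophins and mucins (0.542), cytosolic ribosomal proteins (0.562) and V-ATPase subunits (0.169) had none by either count. The same held for markers of trachea (0.562), germ line (0.627), Malpighian tubules (0.66) and neurons (0.617). The Toll list had a median of -0.02 and a mean of -0.34 against a test pointing up, and the neuronal list a median of -0.01 and a mean of 0.12. Hemocyte and hindgut markers had 2 and 1 tested members, with 0 called, and 0 of 13 ovarian follicle markers were expressed enough to be tested.

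ImdD30A in enterocytes addressed the same question for the absorptive cells that form most of the epithelium. imd rose from 32.0 ± 3.22 to 55.3 ± 0.823 CPM (SD, n = 3 per group; 0.79 ± 0.09, adjusted p = 0.00572) and w, named by the rule for the difference between drivers, from 77.4 ± 3.71 to 281 ± 3.61 CPM (1.86 ± 0.06, adjusted p = 3.37e-05). CG6296 (3R, 27003236 to 27005469) fell from 11.9 ± 0.452 to 0.808 ± 0.432 CPM (-3.85 ± 0.28, adjusted p = 0.00168), and the serine protease gene Ser8 from 228 ± 43.6 to 60.3 ± 25.1 CPM (-1.92 ± 0.28, adjusted p = 0.0107). Mocs1, which acts in molybdenum cofactor synthesis, fell from 50.1 ± 2.64 to 17.1 ± 3.86 CPM (-1.55 ± 0.15, adjusted p = 0.00432). Further large falls were those of CG11889 and CG11891 (same reads, -2.44 ± 0.23), CG16898 (-2.01 ± 0.11), CG12224 (-1.69 ± 0.24) and CG11878 (-1.62 ± 0.17).

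With the Myo1A driver 1007 of 9995 tested genes were called, 527 higher and 480 lower, and 127 changed at least 2-fold (68 higher, 59 lower). The groups did not overlap for 3478 genes, against 10% by chance, and the median SE was 0.11. The 8 largest rises by the naming rule were of genes almost without reads in the controls. CG16826 (2L, 13347773 to 13349020) had 0.0487, 0.0543 and 0 CPM in the controls and 59.4, 404 and 1650 with ImdD30A (adjusted p = 0.00858). whe had 0, 0.136 and 0.0276 CPM against 46.9, 150 and 931 (adjusted p = 0.0093), and lcs 0, 0.271 and 0.0276 against 35.6, 120 and 674 (adjusted p = 0.0105). CG33109 had 0 reads in the controls and 75, 537 and 2280 reads with ImdD30A, at least 1020-fold higher against the floor of 3 counts over the control group. That bound was 312-fold without ImdD30A 3 and 655-fold without control 1. CG45080, CG34212, CG43680 and Mal-B1 followed the same pattern. In the esg libraries these genes ranged as widely among replicates, CG16826 from 0.0305 to 409 CPM in the controls and from 0.378 to 570 with ImdD30A. edgeR called 0 of 11 genes of this kind there, with 1 at an unadjusted p below 0.05, and DESeq2 called 0. limma-voom ended the call of CG16826 (highest adjusted p = 0.188 over the alternatives), whe (0.171) and lcs (0.184).

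**Figure D1:**
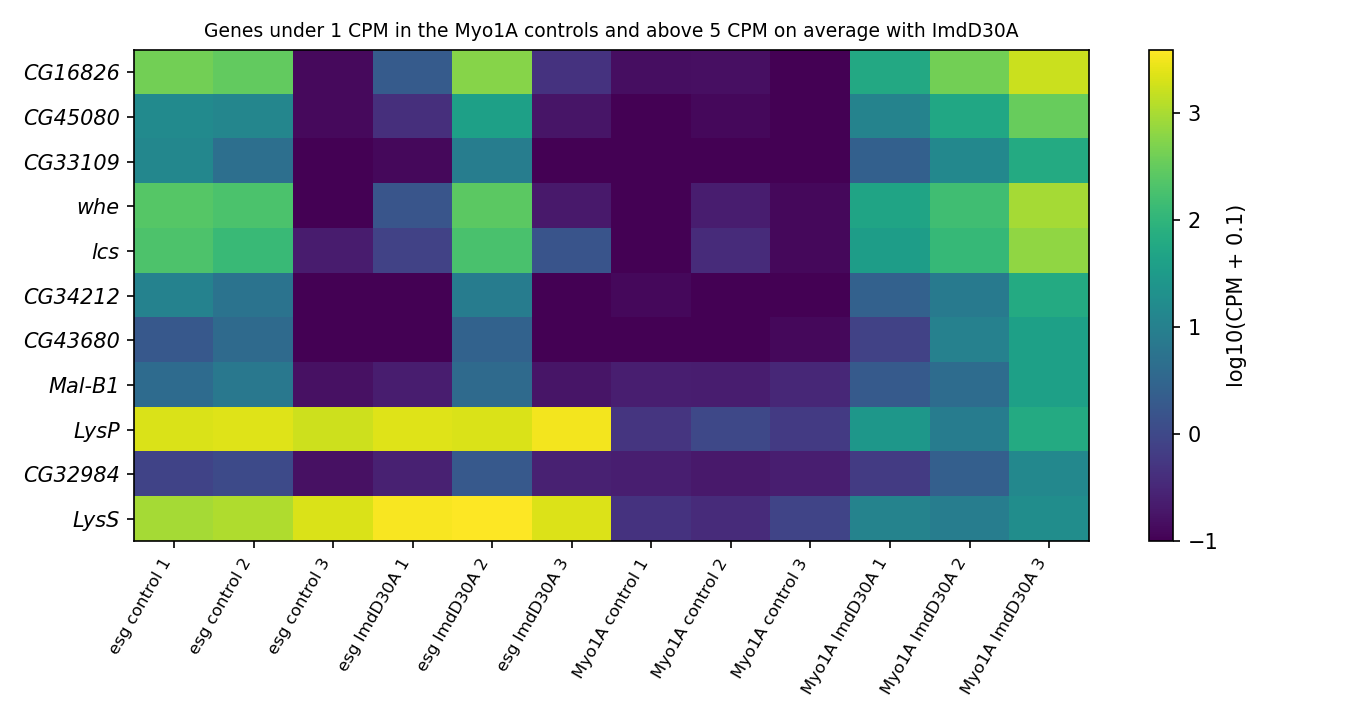
CPM (colour, log10 of CPM plus 0.1) of the 11 genes (vertical axis) that were below 1 CPM in each Myo1A control and at 5 CPM or more on average in Myo1A with ImdD30A, in each of the 12 libraries (horizontal axis). CG16826 spans 0.0305 to 409 CPM within the esg controls, while LysP is at 1690 CPM or above in all 6 esg libraries and below 1 CPM in the 3 Myo1A controls.

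Leaving out 1 library changed the Myo1A count of called genes to 425 (without control 1), 321 (control 2), 615 (ImdD30A 1), 121 (ImdD30A 2) or 353 (ImdD30A 3). Of the 79 called genes that the naming rule took for this driver, 28 kept their call whichever library was left out, among them GstE1, FASN1, S6k and Cat. Without control 1, 2 and 3 it was lost by 26, 35 and 12, and without ImdD30A 1, 2 and 3 by 20, 50 and 30. The genes near 0 in the controls made up 11 of the called rises, and 996 called genes were left without them.

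Glutathione S-transferases fell most clearly of the lists with the Myo1A driver: 11 of 31 over all genes, 18 adjusted over the list alone, none higher (list adjusted p = 6.59e-14). Alone among the lists of either driver, their call held with an estimated correlation (adjusted p = 0.0301). GstE1 and GstE8 lie next to imd, as given above, and such neighbours are not independent cases. A local cause shared by them was not tested. GstE1 went from 17.3 ± 1.63 to 6.43 ± 0.427 CPM (-1.43 ± 0.10, adjusted p = 0.00131), GstS1 from 171 ± 10.5 to 67.2 ± 12.7 CPM (-1.34 ± 0.13), GstE7 from 151 ± 8.71 to 68.6 ± 10.8 CPM (-1.14 ± 0.12) and GstE8 from 81.1 ± 7.58 to 38.2 ± 2.15 CPM (-1.08 ± 0.09). Cytochrome P450 genes fell in 16 of 71 cases and 1 rose (20 and 3 adjusted over the list alone; list adjusted p = 8.17e-05; adjusted p = 0.338 with an estimated correlation). Cyp309a1 went from 227 ± 15.3 to 101 ± 4.83 CPM (-1.17 ± 0.08, adjusted p = 0.00126). Cyp6a23 fell by 0.87 ± 0.07 and Cyp9b2 by 0.76 ± 0.07, while Cyp6a18 rose by 1.15 ± 0.12. UDP-glycosyltransferases fell in 7 of 15 cases, 8 adjusted over the list alone, among them Ugt86Da (214 ± 3.93 to 142 ± 13.1 CPM, -0.59 ± 0.08, adjusted p = 0.00876; list adjusted p = 0.000184; adjusted p = 0.338 with an estimated correlation). Redox genes fell in 6 of 16 cases over all genes (1 higher and 7 lower adjusted over the list alone; list adjusted p = 0.031; adjusted p = 0.338 with an estimated correlation), including the catalase gene Cat (515 ± 16.2 to 365 ± 23.3 CPM, -0.50 ± 0.07), the peroxiredoxin gene Jafrac1 (-0.68 ± 0.10) and GstD1 (-0.67 ± 0.09). The redox list call ended without ImdD30A 1 (0.0596) or control 3 (0.344). GstE1, GstS1, GstE7, GstE8, Cyp309a1, Cyp6a23, Cyp9b2, Cyp6a18, Ugt86Da, Cat and GstD1 kept their call without any 1 library.

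**Figure D2:**
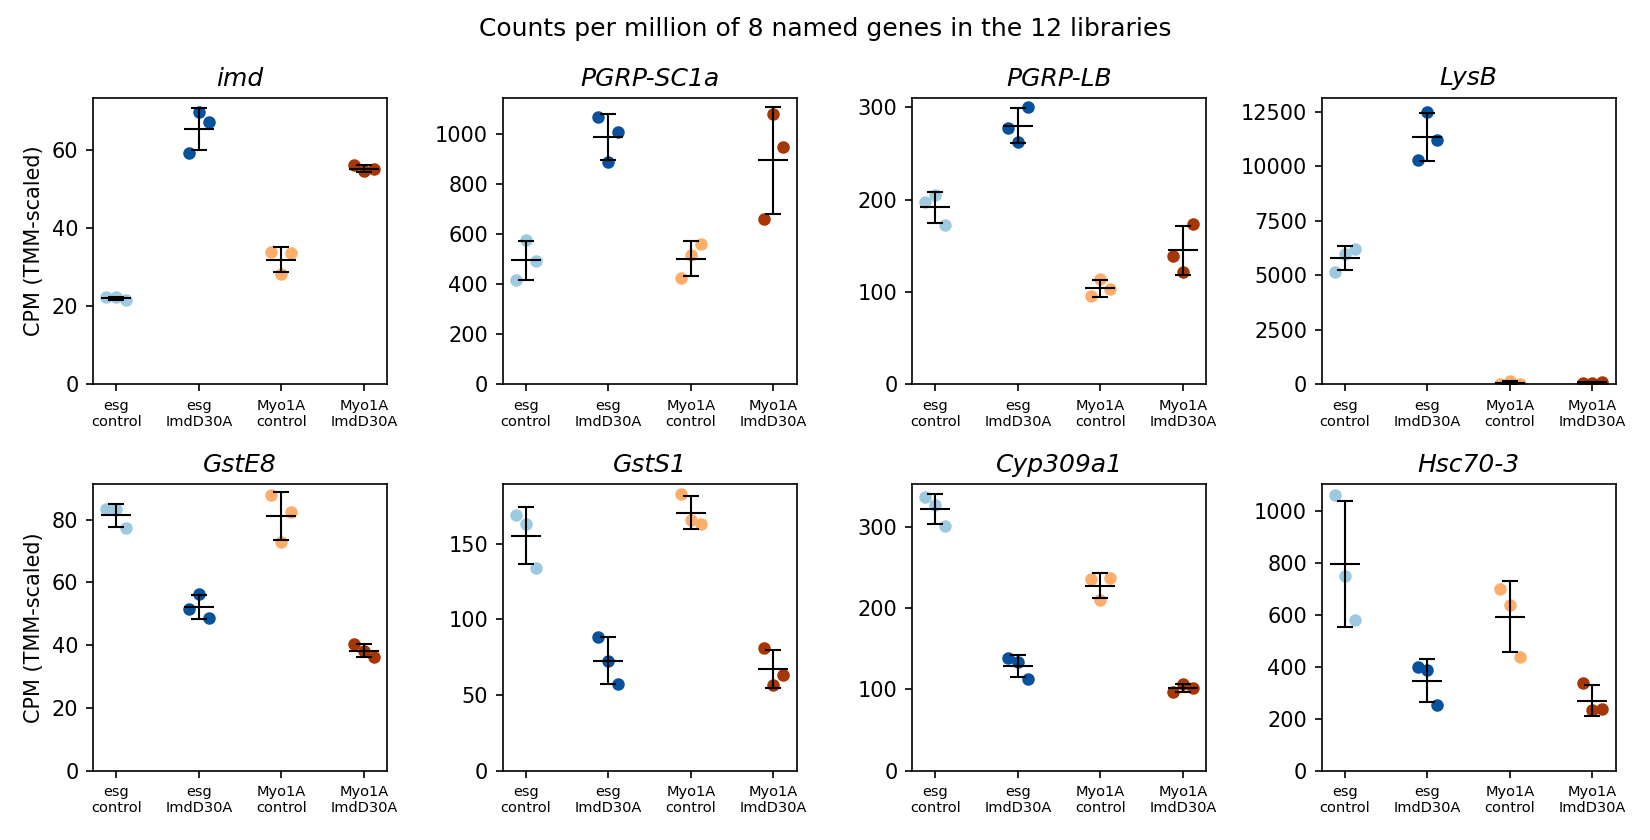
TMM-scaled CPM (vertical axis, from 0) of 8 named genes in the 4 groups (horizontal axis); each point is 1 library and bars are mean ± SD (n = 3). GstE8 lies at 52.2 ± 3.76 CPM in esg with ImdD30A and 38.2 ± 2.15 in Myo1A with ImdD30A, against 81.4 ± 3.54 and 81.1 ± 7.58 in the controls.

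Unfolded protein response genes fell with the Myo1A driver, 8 of 14 over all genes and 9 adjusted over the list alone (list adjusted p = 1.65e-05; adjusted p = 0.338 with an estimated correlation). Hsc70-3 went from 592 ± 136 to 269 ± 59.7 CPM (-1.14 ± 0.20, adjusted p = 0.0176), CaBP1, a protein disulphide isomerase, from 147 ± 32.1 to 71.0 ± 14.6 CPM (-1.05 ± 0.19) and Herp from 129 ± 27.7 to 75.4 ± 5.8 CPM (-0.77 ± 0.15). Heat shock genes rose as a list with 0 of 15 called over all genes and 5 adjusted over the list alone (median 0.62, list adjusted p = 0.00129; adjusted p = 0.562 with an estimated correlation); Hsp70Bc had 5.21 ± 1.65 CPM in the controls and 16.4 ± 9.34 with ImdD30A (1.66 ± 0.43, adjusted p = 0.0509). Cytosolic ribosomal proteins and respiratory chain genes were slightly lower as lists. Both had a median of -0.12. Of 85 and 67 members 0 were called by either count, with list adjusted p = 0.000234 and 0.000948 (adjusted p = 0.678 and 0.59 with an estimated correlation). V-ATPase subunits, of the proton pump, fell in 2 of 23 cases by either count, Vha100-2 (-0.42 ± 0.08, adjusted p = 0.0218) and Vha100-5 (-0.25 ± 0.06; list adjusted p = 0.0214; adjusted p = 0.582 with an estimated correlation), and without ImdD30A 1 the list had adjusted p = 0.09.

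Among Imd genes in the Myo1A comparison, Rel rose from 126 ± 28.5 to 209 ± 20.6 CPM (0.73 ± 0.16, adjusted p = 0.0337), and the receptor gene PGRP-LC fell from 18.7 ± 0.628 to 14.6 ± 0.0906 CPM (-0.36 ± 0.07, adjusted p = 0.019). The signalling list did not pass (2 of 16 higher and 1 lower by either count, list adjusted p = 0.295). The amidase genes PGRP-SC1a (502 ± 70.1 to 895 ± 214 CPM, 0.84 ± 0.18, adjusted p = 0.0306) and PGRP-SC1b (0.67 ± 0.16, adjusted p = 0.0375) rose among 12 negative regulators, 4 adjusted over the list alone (list adjusted p = 0.0294; adjusted p = 0.458 with an estimated correlation). That list call ended without ImdD30A 3 (0.0527). In the Toll list, which did not pass (adjusted p = 0.782), SPE, the protease that activates the Toll ligand, fell from 1.04 ± 0.0398 to 0.385 ± 0.151 CPM (-1.42 ± 0.33, adjusted p = 0.0368) and CG15067 rose (2.70 ± 0.62); adjusted over the list alone 2 rose and 2 fell.

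Digestive genes in the Myo1A comparison included falls of Amy-p (16000 ± 1450 to 12500 ± 226 CPM, -0.35 ± 0.09, adjusted p = 0.0449), Amy-d (-0.51 ± 0.08) and Mal-A8 (-0.38 ± 0.09). In that list 3 of 18 fell and 1 rose over all genes (12 and 2 adjusted over the list alone; list adjusted p = 0.000794, pointing down; adjusted p = 0.458 with an estimated correlation); its median was -0.31 and its mean 0.11, raised by Mal-B1, which was near 0 in the controls. Proteases did not pass as a list (adjusted p = 0.0518), with 3 of 30 lower over all genes and 1 higher and 3 lower adjusted over the list alone, among them Jon99Ci (2800 ± 102 to 1870 ± 133 CPM, -0.58 ± 0.08, adjusted p = 0.00837). Lysozymes rose as a list (2 of 7 by either count, list adjusted p = 0.000237; adjusted p = 0.338 with an estimated correlation) through LysS (0.47 ± 0.267 to 12.5 ± 4.63 CPM, adjusted p = 0.00235) and LysP (0.602 ± 0.258 to 33.0 ± 28.6 CPM, adjusted p = 0.0106), the latter not called by limma-voom (highest adjusted p = 0.097). Jon99Ci and LysS kept their call without any 1 library.

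Regional transcription factors rose with the Myo1A driver. Of 7 such factors 4 rose by either count (list adjusted p = 0.000909; adjusted p = 0.338 with an estimated correlation): Ptx1, expressed in the middle midgut (90.8 ± 3.62 to 139 ± 13.8 CPM, 0.61 ± 0.09, adjusted p = 0.0105), tsh (0.78 ± 0.14), hth (0.47 ± 0.11) and cad (0.48 ± 0.09). Enterocyte identity genes passed with 2 of 10 higher by either count, cad and the junction gene mesh (848 ± 55.0 to 1140 ± 20.9 CPM, 0.43 ± 0.07, adjusted p = 0.0135; list adjusted p = 0.0294; adjusted p = 0.338 with an estimated correlation), and without control 1 or control 3 the list had adjusted p = 0.0606 or 0.0657. Adhesion genes rose in 2 of 16 cases over all genes and 5 adjusted over the list alone (list adjusted p = 0.0161; adjusted p = 0.552 with an estimated correlation; 0.132 without control 3): the integrin genes mys (0.47 ± 0.09, adjusted p = 0.0227) and scb (0.47 ± 0.11). Septate junction genes did not pass as a list (adjusted p = 0.129) but 3 of 13 rose by either count, mesh, scrib (0.46 ± 0.07) and cora (0.41 ± 0.07). Insulin and TOR genes rose (2 of 13 over all genes, 2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0144; adjusted p = 0.338 with an estimated correlation) through the kinase gene S6k (162 ± 7.59 to 254 ± 21.9 CPM, 0.65 ± 0.08, adjusted p = 0.00798) and the insulin receptor gene InR (12.8 ± 0.495 to 24.5 ± 4.77 CPM, 0.93 ± 0.14). S6k alone of the genes named here kept its call without any 1 library.

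Markers of other cell types also moved with ImdD30A in the Myo1A comparison, beside the gene groups above. Fat body markers rose, 2 of 4 over all genes and 4 adjusted over the list alone (list adjusted p = 0.000184; adjusted p = 0.338 with an estimated correlation), Yp3 from 6.4 ± 6.44 to 48.4 ± 6.37 CPM (2.93 ± 0.66, adjusted p = 0.0346) and apolpp from 4.13 ± 2.78 to 17.2 ± 5.69 CPM (2.06 ± 0.46, adjusted p = 0.0324). Muscle markers rose, 4 of 11 over all genes and 8 adjusted over the list alone (list adjusted p = 8.17e-05; adjusted p = 0.338 with an estimated correlation), among them Mhc, myosin heavy chain (97.8 ± 5.65 to 147 ± 14.6 CPM, 0.58 ± 0.09, adjusted p = 0.012), and the giant muscle proteins sls (0.89 ± 0.17) and bt (0.68 ± 0.11). Malpighian tubule markers did not pass (adjusted p = 0.0743), with Oatp58Dc (1.49 ± 0.23) and Oatp58Db (1.16 ± 0.29) higher and Irk1 lower (-0.46 ± 0.10) by either count. Of 3 hemocyte markers Pxn, peroxidasin, fell by either count (-0.62 ± 0.11; list adjusted p = 0.248, pointing down, with a mean of 0.63 and a median of -0.15). Markers of trachea (list adjusted p = 0.782), germ line (0.792) and neurons (0.755) had 0 called members, as had the 1 tested hindgut marker, and 0 of 13 follicle markers were tested.

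Other lists did not pass with the Myo1A driver. Lipid synthesis genes had 2 of 11 higher, and 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0544): FASN1, fatty acid synthase, went from 145 ± 14.5 to 284 ± 33.5 CPM (0.97 ± 0.11, adjusted p = 0.00572) and Lpin rose by 0.42 ± 0.10. In the lipolysis and lipid transfer list (adjusted p = 0.0544; 4 higher and 2 lower adjusted over the list alone) LpR1 rose (0.50 ± 0.09, adjusted p = 0.0162) and the lipase gene mag fell (-0.32 ± 0.08, adjusted p = 0.0444). By either count 1 member rose among EGF receptor pathway genes, Ras85D (0.36 ± 0.07; list adjusted p = 0.0743), and among progenitor markers, mira (6.63 ± 0.89 to 12.2 ± 0.591 CPM, 0.88 ± 0.11, adjusted p = 0.00804; list adjusted p = 0.623, pointing up with a median of -0.03). No member was called over all genes among JAK-STAT genes (list adjusted p = 0.9, pointing up with a median of -0.06; 1 higher adjusted over the list alone), Notch targets (0.9), cell cycle genes (0.895), enteroendocrine genes (0.895, pointing up with a median of -0.01) and peritrophins and mucins (0.168). FASN1 and mira kept their call without any 1 library.

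**Figure D3:**
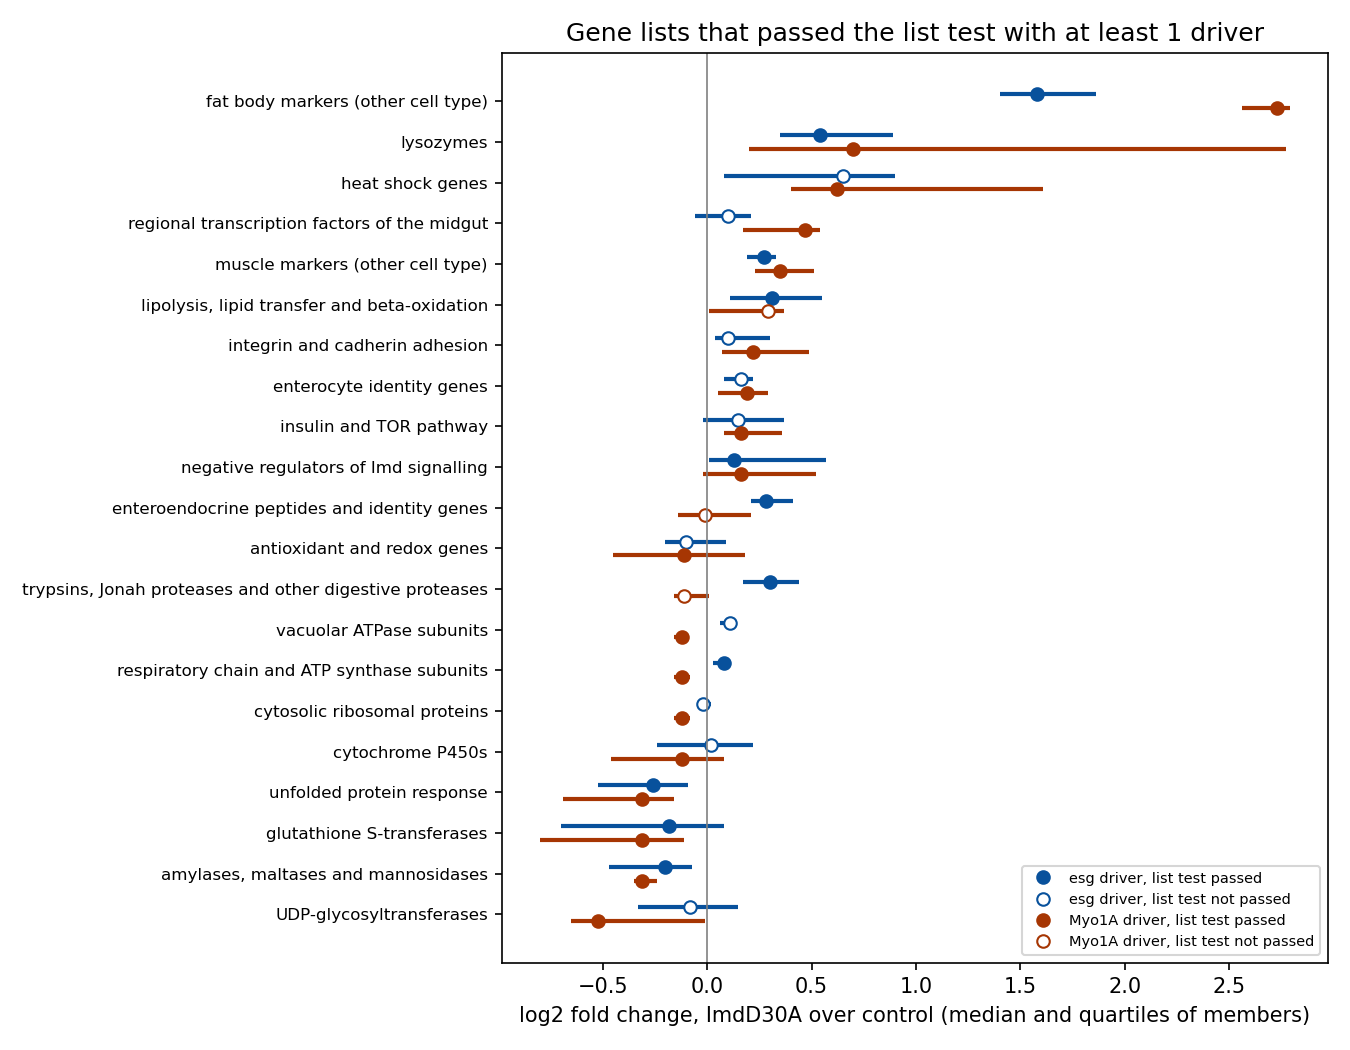
Median (points) and quartiles (lines) of log2 fold changes with ImdD30A (horizontal axis) of the members of each list (vertical axis) that passed the list test with at least 1 driver; filled points passed with that driver. Proteases have a median of 0.30 with the esg driver and -0.11 with the Myo1A driver, and the lists differ in size.

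Calls with both drivers overlapped far beyond independent lists. Detoxification genes stood among the shared falls, such as GstE1 (-1.41 and -1.43 with esg and Myo1A), GstS1 (-1.10 and -1.34), GstE8 (-0.64 and -1.08), Cyp309a1 (-1.32 and -1.17) and Ugt37b1 (-1.11 and -1.15), with Hsc70-3 and Herp beside them. Shared rises included mira (1.09 and 0.88), PGRP-SC1a (1.0 and 0.84), LpR1 (0.64 and 0.50) and the fat body marker Yp3 (1.86 and 2.93). Among 9841 genes tested with both drivers, 207 and 521 were higher and 77 were higher with both, against 11 from independent lists (odds ratio 12.3, 95% interval 9.0 to 16.6, Fisher's exact p = 5.98e-46). In the other direction 208 and 480 were lower and 101 were lower with both, against 10.1 (odds ratio 23, 95% interval 17 to 31.1, Fisher's exact p = 1.95e-78). The comparisons share no library, and genes are not independent of one another. Among 1233 genes called with either driver, 1065 (86.4%) had the same sign in both; across all genes Pearson's r of the fold changes was 0.279 and Spearman's rho 0.434. For the 178 genes called the same way with both drivers the count was 461 with DESeq2, and leaving out 1 library gave 53 (Myo1A ImdD30A 2), 61 (esg control 2), 67 (esg control 1), 87 (esg ImdD30A 2), 91 (Myo1A ImdD30A 3), 93 (Myo1A control 2), 96 (esg ImdD30A 1), 112 (Myo1A control 1) or 113 (esg ImdD30A 3).

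**Figure D4:**
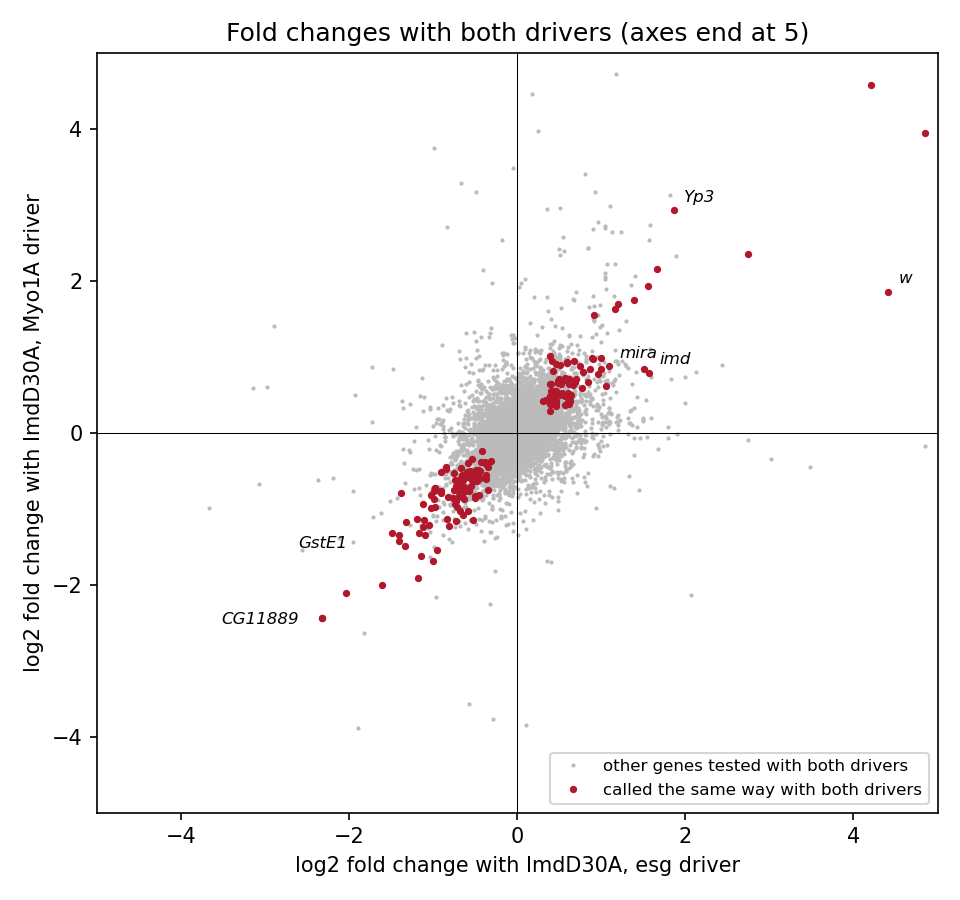
Log2 fold change with ImdD30A with the esg driver (horizontal axis) and the Myo1A driver (vertical axis), 1 point per gene tested with both; red points are the 178 genes called the same way with both. The axes end at 5 in each direction and leave out 15 genes, 0 of them red; w lies at 4.41 and 1.86.

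The test of the difference between drivers called 34 of 10402 genes, 17 with a more positive effect with the Myo1A driver and 17 with a more negative one. w had the clearest difference, -2.56 ± 0.10 (adjusted p = 1.93e-07), followed by CG6296 (-3.95 ± 0.33, adjusted p = 0.000295) and CG13313 (-1.92 ± 0.19, adjusted p = 0.00153). The control levels of w were unlike, 11.3 ± 1.11 CPM with the esg driver and 77.4 ± 3.71 with the Myo1A driver. With ImdD30A they were closer, 241 ± 10.9 and 281 ± 3.61 CPM. CG13313 went from 0.707 ± 0.163 to 2.66 ± 0.373 CPM with the esg driver and from 16.9 ± 0.445 to 16.7 ± 1.02 with the Myo1A driver. Jon99Fi, a Jonah protease gene, rose with the esg driver and had a log2 value of -0.16 with the Myo1A driver, a difference of -1.12 ± 0.17 (adjusted p = 0.0203). More positive with the Myo1A driver were LysP (5.45 ± 0.85, adjusted p = 0.0214), LysS (3.54 ± 0.61, adjusted p = 0.0366), Fib, which encodes the nucleolar protein fibrillarin (0.88 ± 0.16, adjusted p = 0.0434), and Prosap (0.81 ± 0.15, adjusted p = 0.0434). The lysozyme genes started from unlike levels, LysP at 2020 ± 307 CPM in the esg controls and 0.602 ± 0.258 in the Myo1A controls, and LysS at 1390 ± 654 and 0.47 ± 0.267. LysS stood at 3150 ± 857 CPM in esg with ImdD30A and 12.5 ± 4.63 in Myo1A with ImdD30A. imd, chosen after its values were seen, rose less with the Myo1A driver (-0.78 ± 0.11, adjusted p = 0.0203). Of the 178 genes called the same way with both drivers 2 differed by this test, and 5 genes were called in opposite directions. These were Nopp140, Gp210, CG30349 and Ranbp21 (lower with esg, higher with Myo1A) and CG6067 (the reverse), named after their values were seen.

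Without 1 library the count of differing genes was 8 (Myo1A control 1), 16 (Myo1A control 2), 53 (Myo1A control 3), 11 (Myo1A ImdD30A 2), 8 (Myo1A ImdD30A 3), 16 (esg control 1), 6 (esg control 2), 7 (esg control 3) or 7 (esg ImdD30A 2), and DESeq2 called 383. The even split of directions depended on the libraries: 5 were more positive and 20 more negative without Myo1A ImdD30A 1, 1 and 6 without esg ImdD30A 2, and 32 and 21 without Myo1A control 3. DESeq2 gave 166 and 217. With the replicate number as a block 3 genes were called, 0 more positive and 3 more negative, and 5 of the 8 genes named by the rule lost their call. w, CG6296 and CG13313 kept their call without any 1 library. Fib, Jon99Fi, LysP, LysS and Prosap lost it in at least 1 such fit, with highest adjusted p over the alternatives of 0.146, 0.0768, 0.21, 0.238 and 0.115. In a list test chosen after seeing the data, digestive proteases differed between the drivers (median difference -0.35, 0 of 30 more positive and 1 more negative over all genes, 19 more negative adjusted over the list alone, list adjusted p = 3.11e-16; adjusted p = 0.0228 with an estimated correlation).

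Set beside the authors' deposited table, the fold changes had r = 1.0 across genes with either driver. At an FDR below 0.05 the authors' deposited table held 728 genes for the esg driver (361 higher, 367 lower), of which 371 were also called here in the same direction. For the Myo1A driver the authors' deposited table held 1306 genes (673 higher, 633 lower), of which 911 were also called here. Called here but not there were 48 genes with the esg driver, among them LysB (FDR 0.248) and LysD (0.26). With the Myo1A driver they were 96, among them Mhc (0.0855), bt (0.0952) and Amy-p (0.0983). The fit of all 12 libraries made here shared 557 and 1184 of the authors' calls.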

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

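The tests of the near-zero genes, of the stock's background and of the yolk protein genes, and the list tests on the difference between drivers, were chosen after the results were seen. The effect of ImdD30A differed between the drivers for 34 genes in the interaction test, and these results stand here because of that difference. More positive with the Myo1A driver were the lysozyme genes LysP (log2 difference 5.45) and LysS (3.54), the nucleolar gene Fib (0.88) and Prosap (0.81), which encodes a synaptic scaffold protein. For LysP and LysS the log2 difference rests on a Myo1A control level near 0 (0.602 and 0.47 CPM, against 2020 and 1390 in the esg controls), and for CG13313 on an esg control level below 1 CPM (0.707, against 16.9 in the Myo1A controls). More negative were CG6296 (-3.95), w (-2.56), CG13313 (-1.92) and the protease gene Jon99Fi (-1.12). Of the lists, 10 passed on the difference with the preset correlation, and digestive proteases alone passed with an estimated correlation (adjusted p = 0.0228, median -0.35). Of 100 relabellings of control and ImdD30A within each driver, the real one included, 4 called at least 34 genes, a share below 0.05. Relabelling also breaks up the response that the drivers share and mixes it into the spread within groups. It therefore cannot exclude chance as the source of a count of differences. The count itself is unstable: it ran from 6 (without esg control 2) to 53 (without Myo1A control 3) with 1 library left out. With the replicate number as a block it was 3 (0 more positive, 3 more negative). The highest other relabelling called 2074 genes and exchanged control and ImdD30A in all Myo1A libraries alone. It therefore adds the effects of the drivers and points to the response that they share. The other relabellings above 34 genes made the same exchange in the Myo1A libraries, with 1 library of each esg group also exchanged. For w and imd, the transgene and its marker are read together with the native gene, and the control lines of the drivers differ in their insertions.

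For the 178 genes called the same way with both drivers, such as GstE1 and Cyp309a1, an arbitrary grouping of the libraries is argued against. In 1 of 100 relabellings, the real one, as many genes were shared, and the highest other gave 10. Relabelling also breaks up the response within each driver, so it cannot show how far 2 real responses would overlap by chance. Variants linked to the insertion on chromosome 3 that act on genes of that chromosome alone are argued against as the whole cause. Of the 178 genes 76 (42.7%) lay on it, against 43.4% of the others (odds ratio 0.97, 95% interval 0.71 to 1.32, Fisher's exact p = 0.879). A linked variant that acts on genes of other chromosomes would not raise this share, so the test cannot decide on it. The genetic background of the UAS-ImdD30A stock, acting without the driver, stays open, because no group carried the insertion without a driver. Between drivers 2 of the 178 genes differed in effect, imd and w, the transgene and its marker, which decides little for genes chosen as called the same way and a test that recovered 10.4% of simulated 1.5-fold differences. An effect of ImdD30A in both cell types, the biological explanation that the design gives, may give the same pattern and cannot be told apart from that background here.

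The 11 genes near 0 in the Myo1A controls, among them CG16826, whe, lcs and Mal-B1, made up 16.2% of the at least 2-fold rises with that driver. Within both esg groups 9 of the 11 spanned at least 8-fold between replicates, against 13 of 9830 other genes (0.13%), and LysP and LysS did not. Another tissue present in some dissected samples and absent from others is a candidate explanation for those 9, and which tissue was not tested. That their expression needs ImdD30A is argued against, because 10 of the 11 (CG32984 excepted) reached 1 CPM in at least 1 esg control, where no ImdD30A was present. Whether ImdD30A in enterocytes also raised them stays open, since the set was chosen by its levels in the same Myo1A libraries.

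The yolk protein gene Yp3 rose with both drivers (with the esg driver 5 of 14 alternatives ended the call, the highest adjusted p = 0.0818 in the fit of 12 libraries), while Yp1 and Yp2 were called with neither (adjusted p = 0.396 and 0.115 with esg, 0.0859 and 0.0741 with Myo1A). Fat body tissue in the samples is a candidate source: apolpp, which the fat body expresses strongly, rose with the Myo1A driver by 2.06 on the log2 scale but was not called with the esg driver (1.40, adjusted p = 0.0753). Ovarian follicle cells, which also make yolk proteins, are argued against, because the highest mean of a follicle marker with ImdD30A was 0.205 CPM (yellow-g). Of the 10 fat body markers, 5 were expressed enough to be tested with the esg driver and 4 with the Myo1A driver. Expression of these genes in the gut itself was not tested.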

How the results depend on the processing

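Leaving out ribosomal RNA features was chosen after seeing the data; the other alternatives were not. Of 226 results for single genes, 137 were called and 47 of these kept their call under each alternative run; no called gene changed sign. Over genes and alternatives, 2752 outcomes were the same, 365 lost a call and 71 gained one. Single lists were followed where they passed as reported: 244 outcomes were the same and 46 lost the call.

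Genes called with the esg driver numbered 419 as reported, 957 with DESeq2, 649 in the fit of all 12 libraries, 56 with a minimum fold change of 2, and 106 to 477 with 1 library left out. With the Myo1A driver 1007 were called as reported, 127 with a minimum fold change of 2, and 121 to 1164 with 1 library left out. The difference between drivers gave 34 genes, 383 with DESeq2, 52 with a filter at 1 CPM, 9 with a minimum fold change of 2, and 6 to 53 with 1 library left out. Genes shared by both drivers numbered 178, 461 with DESeq2, 28 with a minimum fold change of 2, and 53 to 217 with 1 library left out. A minimum fold change lowers counts by construction, and for the other changes the cause was not tested.

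Of the lists, 11 passed with the esg driver and 18 with the Myo1A driver, against 0 and 1, glutathione S-transferases, with an estimated correlation.

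Whether the replicate numbers pair the samples stays open, because the labels do not say so. Same-numbered samples had correlations of deviations of 0.03 to 0.32 with the esg driver and 0.099 to 0.113 with the Myo1A driver. Samples with different numbers had -0.396 to 0.25 with the esg driver and -0.08 to -0.015 with the Myo1A driver. As a hint from the data, every Myo1A sample correlated best with its own number, and not every esg sample did. With the replicate block 408 genes were called with the esg driver, 1202 with the Myo1A driver, 230 with both and 3 for the difference between drivers (0 more positive, 3 more negative). The block ended the list calls of the respiratory chain with the esg driver (adjusted p = 0.064), and of enterocyte identity (0.051), redox (0.0633) and V-ATPase genes (0.051) with the Myo1A driver. For the difference in ribosome biogenesis genes, the camera test with an estimated correlation gave 0.0591 under the block.

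Uncalled genes reversed in 7 outcomes, each with 1 library left out. With the esg driver, Pxn ranged from -0.146 to 0.019 on the log2 scale (the latter without ImdD30A 1) and piwi from -0.388 to 0.002 (without control 1). With the Myo1A driver, Drs ranged from -0.324 (without ImdD30A 2) to 3.884, and was -0.142 without control 1 and -0.022 without control 3. E(spl)malpha-BFM ranged from -0.442 to 0.033 (without control 2), and nos from -0.094 (without control 1) to 0.294. Depth limits genes near the floor, such as Drs.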

Other observations

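The comparison of lysozyme levels between drivers and the list of ribosome biogenesis genes were chosen after seeing the data. Of 10 splits of the 6 esg libraries the real one called 419 genes and the highest other 12 (1 of 10 gave as many as the real one). Of 10 splits of the Myo1A libraries the real one called 1007 and the highest other 0 (1 of 10). With 3 libraries against 3, the splits are too few for a share below 0.05.

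Lysozyme genes differed in level between the driver lines, ImdD30A apart. The genes LysB, LysC, LysD, LysE, LysP and LysS, at 3L, 1207371 to 1228238, were the 6 genes with at least 30 CPM in each esg library and a Myo1A control mean below 5% of the lowest esg library. LysD had 16600 ± 721 CPM in the esg controls and 222 ± 125 in the Myo1A controls (SD, n = 3), without TMM scaling. The ratio of control means ran from 75.1 (LysD) to 3640 (LysP). The driver lines differ in stock, and reads of near-identical copies cannot be assigned with certainty.

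Fib, Nopp140 and RpI1, genes of the nucleolus and of RNA polymerase I, had log2 differences of 0.88, 0.78 and 0.50 between drivers. A list of 29 other ribosome biogenesis genes was then written without them. With the esg driver 1 of 29 had a log2 value above 0 (median -0.21, camera p = 9.15e-08; p = 0.217 with an estimated correlation), and with the Myo1A driver 24 of 29 (median 0.27, camera p = 2.52e-05; p = 0.27 with an estimated correlation). For the difference 28 of 29 were above 0, with a median of 0.50 (quartiles 0.39 and 0.58). The camera test with an estimated correlation gave p = 0.0213 for the difference, not adjusted for the other lists. With other scaling, without ribosomal RNA features and with each library left out, that p ran from 0.0133 to 0.0421. With the replicate number as a block it was 0.0591. As a hypothesis, the response of ribosome biogenesis genes to ImdD30A may differ between the drivers. Single genes show it less: edgeR called 4 of 29 higher with the Myo1A driver and 0 with the esg driver. It called 0 for the difference (21 at an unadjusted p below 0.05), limma-voom called 0 and DESeq2 13.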
